A study of Bos taurus with 20 samples.

How the data were processed

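Messenger RNA was measured by sequencing in skeletal muscle of 20 heifer calves, 10 on a High plane and 10 on a Moderate plane of nutrition, with 1 library per calf. Per the labels' protocols, RNA was purified with a column kit that included removal of genomic DNA, and libraries were made from it with a stranded kit; the labels give the molecule as polyadenylated RNA. The submitters' processing notes name FastQC 0.11.8, cutadapt 2.6, STAR 2.6.1, R 3.4 and edgeR 3.5, and the bovine genome build ARS-UCD1.2. The tool that counted reads, the annotation release and the strand setting are not given in the sources used here.

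The deposited table lists 27607 Ensembl gene identifiers and 1 column of values per calf. Its values are not whole counts. They are a normalised signal, in which the authors divided each gene's read count by a scaled library size and multiplied it by 1000000, as the values themselves show. Every value was a whole multiple of what 1 read is worth in its column, to within 0.01 of a read for 100% of values. The whole reads were therefore recovered. TMM factors (trimmed mean of M values, the default scaling of edgeR) recomputed from these reads differed from the factors implied by the deposited column totals by at most 2.75e-11. The unit is called scaled CPM (counts per 1000000 TMM-scaled reads) here. The recovered libraries held 12280289 to 14123113 reads assigned to genes, so 1 read was worth 0.0673 to 0.111 scaled CPM, and a gene with no read in a library may have reached 0.202 to 0.333 scaled CPM there (3 reads). These floors, and the 95% Wilson intervals given for shares of reads, cover counting error only, because the reads carried no molecular identifiers that were used here. Totals count reads assigned to genes, and reads that named no gene were not part of the table. No per-sample column was left unused. The chi-square of the read counts per degree of freedom was 19.6 to 183 in the 90 pairs of libraries within a group. It was 34.1 to 227 in the 100 pairs across the groups, so no 2 libraries agreed within sampling noise. That each calf was counted once rests on the labels, because separate libraries of 1 calf could also differ by more than sampling noise.

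The identifiers were not paired with gene symbols in the table. The gene table used here carries RefSeq names for another assembly, and 0 of its 37063 rows hold an Ensembl identifier. None of the 27607 identifiers could therefore be matched to it. Gene names and positions are therefore not given. The 30 gene lists fixed before the data were examined (contractile, metabolic, growth, stress, immune, RNA quality and other cell type genes, 707 symbols in all), the fixed panel of named genes, and the covariates built from adipocyte, fibre type and blood markers were not analysed here for that reason. No check for RNA of other cell types, GC content or gene length was made either.

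The planned main test was edgeR's quasi-likelihood test on counts. Because the table holds scaled values, the main test was limma (3.58.1, R 4.3.3) with an intensity trend on log2(scaled CPM + 1), with group as the only term, all 20 calves, two-sided, and Benjamini-Hochberg adjustment over all genes tested; a gene was called at an adjusted p below 0.05. Fold changes are on this scale, coded as High minus Moderate, and understate the change of genes at low levels. Genes were kept by edgeR's filterByExpr rule (4.0.16, minimum count 10, smallest group of 10) on the recovered reads, which left 12057 genes. The edgeR quasi-likelihood test was run on the recovered reads as an alternative, added after the data were seen, and is given beside the counts of called genes. The rule for the genes named in the text was the smallest p in each direction among called genes with a symbol; without symbols it was limited to the 2 genes higher and the 2 genes lower with the smallest p.

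Principal components were computed on the 500 most variable of the tested genes. Group differences in component scores, library totals and the share of reads in the 20 most abundant genes were tested by permuting the group labels (100000 resamples, two-sided, scipy 1.17.1), with Benjamini-Hochberg adjustment over these 4 tests. The spread between calves was compared as the median over genes of the log2 ratio of the within-group SDs, with 100 permutations of group-centred values, the observed one included.

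The tests were tested on simulated data. Reads were drawn for the same genes at their observed mean shares of reads and dispersions, with 200 genes changed. Library sizes were the observed totals multiplied by their TMM factors, so they differed from the observed totals. The drawn reads were then turned into scaled values. All simulated reads were recovered exactly. The limma test over 12057 genes recovered 33.3% of 60 genes changed 1.5-fold, 80.8% of 73 genes changed 2-fold and 98.5% of 67 genes changed 3-fold, with no wrong sign, and 3.97% of its calls were false. The likelihood ratio test and DESeq2 made 10.3% and 9.60% false calls in the same simulation, and voom and the edgeR quasi-likelihood test 2.74% and 3.31%. Genes were drawn independently of each other, so these shares do not cover correlation between genes or outlying libraries.

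Alternatives were other scalings (DESeq2 size factors and upper quartile), other tests (DESeq2 1.42.0, limma voom with sample weights, edgeR's likelihood ratio test and a robust quasi-likelihood fit), other filters, other thresholds, a surrogate variable (sva 3.50.0) and leaving out each library in turn. Pseudocounts of 0.1 and 5, the edgeR quasi-likelihood test on recovered reads, the share of the 20 most abundant genes as a covariate and leaving out 2 libraries together were added after the data were seen. Each calf was sampled once, so no block was fitted. The labels give no batch.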

Results

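Skeletal muscle was profiled by RNA sequencing in Angus by Holstein-Friesian crossbred heifer calves reared on either of 2 feeding regimes between 2 and 21 weeks of age. The 10 High plane calves were given 1.5 kg of milk replacer in 10 litres per day with free access to concentrates for 8 weeks, and then concentrates and hay without restriction for 11 weeks. The 10 Moderate plane calves were given 0.5 kg of milk replacer in 4 litres and 1 kg of concentrates per day, and after weaning 1 kg of concentrates with hay. The regimes were set for expected gains of 1.2 and 0.5 kg per day. All calves were sampled at 21 weeks of age, and each contributed 1 library, so the replicate is the animal. The libraries held 13061202 ± 392730 reads assigned to genes in the High plane group and 13132029 ± 412119 in the Moderate plane group (mean ± SD, n = 10 each).

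Of the 27607 genes listed, 19739 had a read in some library and 12057 were abundant enough to be tested. Reads from this muscle were concentrated in few genes. The 20 most abundant genes of each library took 38.1% ± 4.52 of its reads in the High plane group and 37.2% ± 2.45 in the Moderate plane group (SD, n = 10 each). The High plane replicate 2 library had the highest such share, 47.3% (95% Wilson interval 47.27 to 47.33%). A read was found for 15683 ± 429 genes per High plane library and 15773 ± 254 per Moderate plane library (SD, n = 10 each). Neither the share of the most abundant genes (difference of 0.873 percentage points, permutation p = 0.607, adjusted p = 0.775) nor the library total (permutation p = 0.705, adjusted p = 0.775) differed between the groups by more than the spread between calves.

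The comparison of the High with the Moderate plane addressed how the muscle transcriptome differs between the feeding regimes. The regimes ran until sampling, so effects of early feeding cannot be told apart from those of feeding at that age. In the High plane group 138 genes were higher and 120 were lower than in the Moderate plane group, which is 2.14% of the genes tested (limma on log2(scaled CPM + 1), Benjamini-Hochberg adjusted p below 0.05, n = 10 each). Most of these changes were moderate on this scale, which understates the change of genes at low levels. The median change was 1.57-fold among the genes that were higher, with an interquartile range of 1.41- to 1.84-fold and a maximum of 5.27-fold. Among the genes that were lower the median was 1.58-fold, the interquartile range 1.41- to 1.85-fold and the maximum 4.84-fold. These maxima hold for this scale only. For example, gene ENSBTAG00000049852 was 3.35-fold lower on it and 17.5-fold lower in the edgeR fit to the reads. On the log2(scaled CPM + 1) scale a change of 2-fold or more was reached by 21 of the genes that rose and 18 of those that fell. The median log2 fold change of all tested genes was 0.01. TMM scaling centres most genes near no change, so this value cannot show or exclude a shift common to all genes. An unadjusted p below 0.05 was given to 1914 genes, against 603 expected by chance.

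Genes changed in both directions at each of 3 levels of abundance. Among the 1205 most abundant tested genes, with mean levels of at least 78.4 scaled CPM, 21 (1.74%) rose and 15 (1.24%) fell on the High plane. Of the next 4823 genes, with a median level of 24.1 scaled CPM, 52 (1.08%) rose and 41 (0.850%) fell. Of the 6029 genes of lowest abundance, with a median level of 4.02 scaled CPM, 65 (1.08%) rose and 64 (1.06%) fell. In 13 genes the values of the 10 High plane calves did not overlap those of the 10 Moderate plane calves. Of these, 7 were higher and 6 lower on the High plane, and all 13 were among the called genes. Chance gives such a separation in 0.00108% of genes, or 0.131 of the genes tested.

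**Figure D1:**
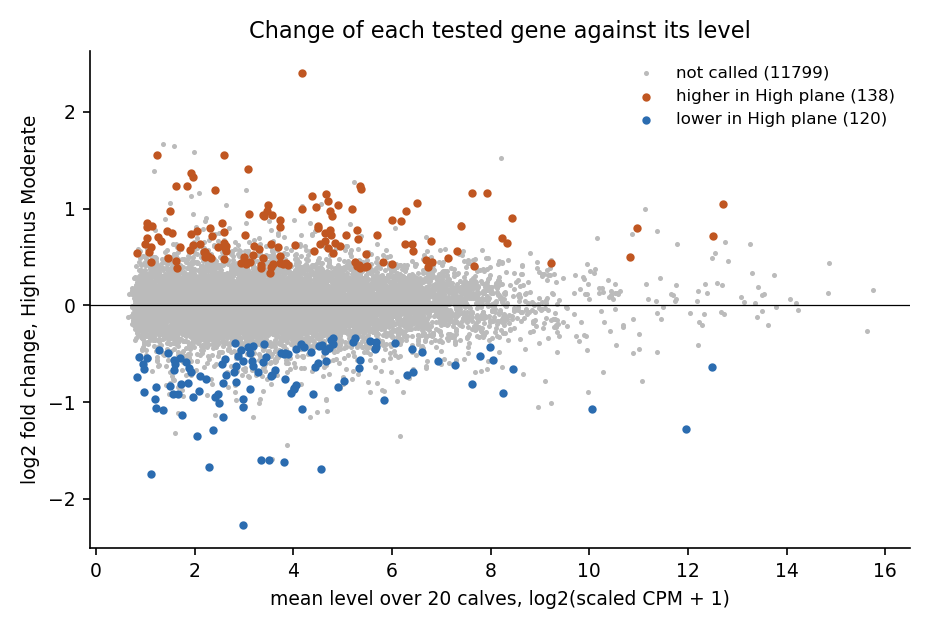
Each point is a tested gene, with its mean level over the 20 calves as log2(scaled CPM + 1) on the x axis and its log2 fold change, High minus Moderate, on the y axis. The 138 genes called higher are orange, the 120 called lower are blue and the other 11799 are grey; called genes lie along most of the range of levels in both directions.

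Gene ENSBTAG00000006686 showed the smallest p and, among the genes called, the largest rise on the log2(scaled CPM + 1) scale. It averaged 44.8 ± 21.9 scaled CPM in High plane calves and 8.04 ± 5.35 in Moderate plane calves (SD, n = 10 each). The log2 fold change was 2.40 ± 0.28 (SE), a 5.27-fold difference, with a limma adjusted p of 1.93e-04. The lowest High plane calf, at 22.7 scaled CPM, lay above the highest Moderate plane calf, at 20.7. Gene ENSBTAG00000020159 rose from 1.06 ± 0.448 to 3.88 ± 1.25 scaled CPM (SD, n = 10 each), a log2 fold change of 1.23 ± 0.16 (SE; limma adjusted p = 2.99e-04), and again the groups did not overlap, with 1.97 as the lowest High plane value and 1.89 as the highest Moderate plane value. At its low level the added pseudocount of 1 shrank the fold, and the ratio of the group means was 3.67.

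Gene ENSBTAG00000013078 was lower on the High plane, at 1.96 ± 1.35 against 8.26 ± 3.12 scaled CPM (SD, n = 10 each). Its log2 fold change was -1.68 ± 0.24 (SE), or 3.19-fold lower on the log2(scaled CPM + 1) scale, with a limma adjusted p of 9.38e-04. In the edgeR fit to the reads it was 4.17-fold lower. Gene ENSBTAG00000049852 was nearly silent on the High plane, with 0.201 ± 0.253 scaled CPM against 3.60 ± 2.75 on the Moderate plane (SD, n = 10 each). Its reads numbered 0 to 11 per High plane library, with 3 libraries at 0, and 5 to 138 per Moderate plane library. The log2 fold change was -1.74 ± 0.26 (SE; limma adjusted p = 9.38e-04) on the log2(scaled CPM + 1) scale and -4.13 in the edgeR fit to the reads. For each of these 2 genes, all 10 High plane calves lay below the Moderate plane mean.

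**Figure D2:**
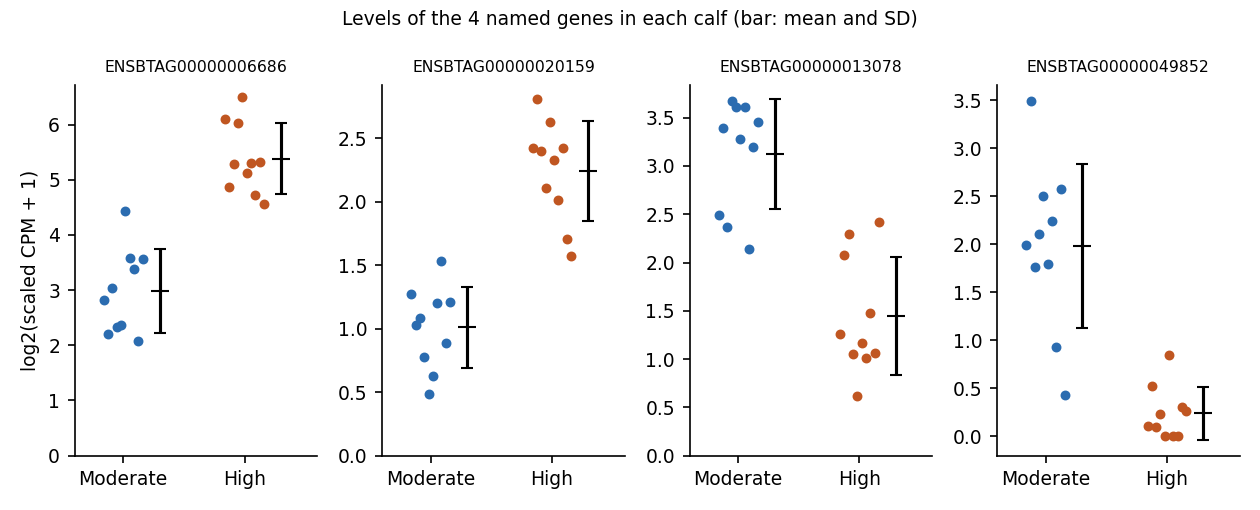
Levels of the 4 named genes as log2(scaled CPM + 1) in each calf (blue points, Moderate plane; orange points, High plane), with a bar for the mean and SD of each group (n = 10). ENSBTAG00000006686 and ENSBTAG00000020159 were higher on the High plane with no overlap between the groups; ENSBTAG00000013078 and ENSBTAG00000049852 were lower, with overlapping values.

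The edgeR quasi-likelihood test on the recovered reads called 167 genes higher and 145 lower (adjusted p below 0.05). It shared 132 of the 138 genes called higher by limma and 116 of the 120 called lower. Some other tests called more: 303 and 302 with DESeq2's Wald test, 358 and 267 with limma voom and 278 and 238 with edgeR's likelihood ratio test. One surrogate variable in the limma fit gave 537 and 386, and testing all genes with a read gave 99 and 81. The High plane replicate 2 and Moderate plane replicate 4 libraries stood apart from the others; without both, limma called 232 genes higher and 187 lower, including 133 and 110 of the genes called with all calves. Leaving out single libraries moved the counts both ways. They fell to 80 higher and 62 lower without Moderate plane replicate 2, to 89 and 77 without High plane replicate 4, to 91 and 78 without High plane replicate 5, to 96 and 77 without High plane replicate 6 and to 99 and 68 without High plane replicate 9, and rose to 209 and 200 without High plane replicate 2.

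The groups overlapped on the first 2 principal components of the 500 most variable genes. The first principal component carried 22.9% of the variance of the 500 most variable genes, and its score was 4.91 ± 7.74 in High plane and -4.91 ± 9.71 in Moderate plane calves (SD, n = 10 each; permutation p = 0.0245, adjusted p = 0.0981), so the difference did not pass after adjustment for the 4 tests. The second component carried 14.3%, with a group difference of 1.05 (permutation p = 0.775, adjusted p = 0.775). The component results depended on the genes or libraries used. On the first component the difference was 7.96 (permutation p = 0.138) with 1000 genes and -1.28 (permutation p = 0.897) with all tested genes. Without High plane replicate 2 and Moderate plane replicate 4 it was 10.6 (exact permutation p = 0.0238). On the second component it was 9.58 (permutation p = 0.0429) with 1000 genes and 22.6 (permutation p = 0.00102) with all tested genes. Without those 2 libraries it was -11.4 (exact permutation p = 0.00103). The components of each set are different axes. The SD of the log2 level of a gene was 0.304 in the High plane and 0.313 in the Moderate plane group in the median, the median ratio of the SDs was 0.958, and the difference was not larger than in permuted groups (p = 0.71, 100 permutations).

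**Figure D3:**
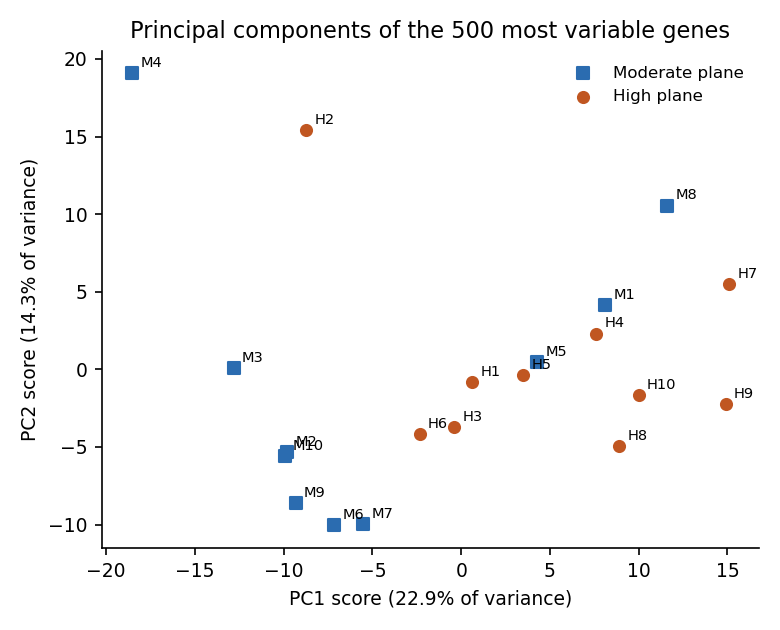
Scores of the 20 libraries on the first (x axis, 22.9% of the variance) and second (y axis, 14.3%) principal component of the 500 most variable genes; H and M with a number give the group and the replicate. The groups overlap, and High plane replicate 2 (-8.73, 15.4) and Moderate plane replicate 4 (-18.5, 19.1) lie at the top left.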

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

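The values of each library and of the 4 named genes were checked in each group of 10 for a value far from the rest, in 22 groups of values. Among independent normal values chance picks out about 1 in 20, and here 4 values were picked out. The groups of values are not independent and include principal component scores, which stretch toward outlying libraries. The 4 values are therefore no test of an excess over chance. The tests of the effect of leaving out the 2 libraries, and of the share of the most abundant genes, on the genes called, and the test of the 2 libraries without the reads of the 500 most abundant genes, were chosen after the result was seen.

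High plane replicate 2 and Moderate plane replicate 4 stood apart from the other calves of their groups. On the main axis of within-group variation over all tested genes, which carried 32.7% of that variance, they scored 62.4 and 59.2, and the nearest calves of their groups scored 12.2 and 21.5. High plane replicate 2 also stood apart on the second component of the 500 most variable genes (15.4, next 5.51). Moderate plane replicate 4 had the largest library (14123113 reads, next in its group 13329794). High plane replicate 2 and Moderate plane replicate 4 each had the fewest genes with a read in their group (14800 and 15305). Each also had the lowest TMM factor of its group (0.668 and 0.899).

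Against the other calves of their own group, 5.78% of genes were over 2-fold higher and 9.34% over 2-fold lower in High plane replicate 2, and 1.94% and 10.5% in Moderate plane replicate 4; in the other libraries 0.929 to 3.97% of genes were off by as much in either direction. Depth did not account for this: after every library was thinned to the smallest total, the lower score of the 2 was still 2.77 times the largest of the others (2.76 before). Nor did the share of reads taken by the most abundant genes: the ratio was 3.18 ± 0.02 (SD over 10 thinnings) after the reads of the 500 most abundant genes were taken out and the other reads were thinned to equal totals and scaled anew. The deviations of the 2 libraries were correlated across genes (r = 0.65; the other 81 pairs across groups ranged from -0.32 to 0.56, median 0.01, and genes are not independent), and 524 genes were over 2-fold lower in both. These values do not decide whether the 2 share a source, because the libraries were picked for lying far out on the same side of one axis, so the correlation is no independent test. Whether they share one, and whether it is the sampling site, other tissue in the sample, RNA quality or the animals is open. No biological explanation was tested, as the genes carry no names here.

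The genes called between the feeding groups were not owed to these libraries. Without them 419 genes were called in place of 258, which argues against them as the source of the calls. With the share of the 20 most abundant genes as a covariate 531 genes were called. That share hardly differed between the groups (permutation p = 0.607), so the covariate had little group difference to absorb. Its count therefore does not bear on the source of the calls. Of 100 splits of the 20 libraries into 10 and 10, only the real one (1 of 100) gave as many genes in a direction, both for the 138 higher and for the 120 lower; the highest of the other splits was 2 genes. A chance division of the calves is thus an unlikely source of the number of called genes, at a share of 1 in 100, the smallest that 100 splits can give. The splits say nothing of other differences that follow the feeding groups.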

How the results depend on the processing

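Of the 258 called genes, 0 were called in the opposite direction under any setting. Each setting refitted the same calves or most of them, so such a call was unlikely from the start. Changes of sign without a call were not counted. All 4 named genes stayed past the threshold in their direction under each alternative that tested them (34 or 35 each, highest adjusted p 0.00416, limma with a pseudocount of 5). They were picked for the smallest p in the same libraries, so this does not speak for the other called genes. The numbers of genes called changed with the setting. Genes higher and lower numbered 303 and 302 with DESeq2's Wald test, 358 and 267 with limma voom and sample weights, 278 and 238 with edgeR's likelihood ratio test, and 537 and 386 with one surrogate variable; all 138 and 120 genes were among those called by DESeq2, the likelihood ratio test and the surrogate variable fit, and 136 and 118 among those of voom. They numbered 263 and 234 at an adjusted p below 0.10, and 88 and 72 with a change of at least 1.5-fold on the log2(scaled CPM + 1) scale. Of the settings added after the data were seen, the share of the 20 most abundant genes as a covariate gave 291 and 240, and leaving out both libraries that stood apart gave 232 and 187 with limma and 245 and 229 with edgeR. The other scalings, filters and pseudocounts and the edgeR quasi-likelihood fits stayed within 1.5 times, from 99 to 167 higher and 81 to 145 lower. Leaving out 1 library gave 80 to 209 genes higher and 62 to 200 lower, and the causes were not tested. The counts rose by over 1.5 times without High plane replicate 2 (209 and 200). They fell by as much in both directions without Moderate plane replicate 2 (80 and 62), High plane replicate 4 (89 and 77) and High plane replicate 5 (91 and 78), and in the lower genes alone without High plane replicate 6 (77) and High plane replicate 9 (68). The group difference on the first component depended on the genes used: 9.82 with 500 genes, 7.96 (permutation p = 0.138) with 1000 and -1.28 (p = 0.897) with all; without the 2 libraries it was 10.6 (p = 0.0238). On the second it was 9.58 (p = 0.0429) with 1000 genes, 22.6 (p = 0.00102) with all, and -11.4 (exact permutation p = 0.00103) without the 2 libraries; components of different gene sets are different axes. Depth limits genes near the floor of 3 reads, and genes changed 1.5-fold were recovered in 33.3% of simulated cases.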

Other observations

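The scoring of single calves, the comparison with lists from other splits and the search for gaps were chosen after the data were seen. Each calf was left out in turn, genes were called from the other 19, and the calf was placed between the 2 group means over those genes. By this measure 18 of 20 calves fell on the side of their own group (9 in each group). The exceptions were High plane replicate 2 (median score -0.15, where 1 is the High and -1 the Moderate mean of the other calves) and Moderate plane replicate 8 (0.03). Of those on their own side, the nearest to 0 were Moderate plane replicate 1 (-0.16), about as close as the first exception, and High plane replicate 10 (0.27). The strongest scores were those of High plane replicate 4 (1.07) and Moderate plane replicate 2 (-1.79).

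Whether the genes called between the feeding groups vary together within groups was not decided. The mean correlation between genes within groups was 0.132 for the 138 genes that rose and 0.118 for the 120 that fell. Random lists matched on abundance reached at most 0.036 and 0.047, but they mix directions and are no fair comparison for genes picked for a shared direction in the same calves. Lists of the same sizes with the smallest p in one direction were therefore taken from 99 other splits of the calves, after the group means were removed. Of these 198 lists, 108 had a correlation as high as that of the genes that rose, and 125 as high as that of the genes that fell (medians 0.140 and 0.139). The other splits called at most 2 genes in a direction, so their lists were picked mainly on variation between calves. A correlation no higher than theirs therefore does not show that the called genes vary independently. Without the 2 libraries that stood apart the values were 0.161 and 0.104, reached by 43 and 99 of the 198 lists (highest 0.342 and 0.341), so the part of these libraries in the correlations was not decided.

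In 6 tested genes the calves lay on either side of a gap of at least 4-fold, with at least 4 calves on each side. None of the 6 was called between the feeding groups.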
